A study of Homo sapiens with 3 samples.

How the data were processed

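Gene expression was measured on Illumina bead arrays in LNCaP cells after 24 h with ethanol as the vehicle or with bufalin at 10 or 20 nM. Each treatment had 1 array, so the design holds 3 arrays and no replicates. No difference given here has a replicate check, and no p-value, standard error or test between treatments was computed. Groups were taken from the treatment in the labels, and 3 comparisons were made: 10 nM against vehicle, 20 nM against vehicle, and 20 nM against 10 nM.

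RNA was isolated with a column kit and its integrity was checked, per the labels' protocols. The deposited array table gives a signal intensity on a linear scale for each of 47323 probes on each array, and per the file headers these intensities are not normalized. It also gives a deposited detection p-value for each probe and array. BeadStudio 3.0 was used, per the submitters' processing notes, and whether it subtracted background is not given in the sources used here. The lowest intensity on the vehicle array was 91.8 and the median over all probes was 119.5, so the deposited intensities were treated as holding their background.

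A second deposited table holds intensities of 13753 probes. All 41259 of its values are exactly equal, with no tolerance, to those of the larger table, so it is a part of the same unnormalized data and not a separate processing. A rule found from the values gave 13752 of its probes and no others: detection p-value below 0.05 on at least 2 arrays and an intensity at least 10% away from vehicle at either dose. Only 1 probe lay outside this rule.

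Gene names were at hand only for that second table, through a table of probes and genes, so every gene named here had already passed a filter for a difference from vehicle. Of its probes, 10952 had 1 gene symbol, 2 had several symbols and were not named, and 2799 had no gene in the annotation. Symbols were updated by gene identifier against the RefSeq table of human genes, where 10947 identifiers were found and 7 were not. This gave 8661 named genes, of which 1939 had at least 2 probes, and left 36371 of the 47323 probes unnamed here. No genome build is stated for the probes, and no coordinates are given.

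Background was removed with the normexp model fitted from the detection p-values (limma 3.58.1 in R 4.3.3). The fitted mean background signal was 112.9 on the vehicle array, 113.6 on the 10 nM array and 115.8 on the 20 nM array. An offset of 16 was added, the 3 arrays were quantile normalized over all probes, and log2 was taken. Fold changes are on this offset scale, which understates the differences of dim genes. A gene was represented by its named probe with the highest mean, and was counted as detected in a comparison when that probe had a detection p-value below 0.01 on at least 1 of the 2 arrays. The size threshold was 2-fold, a log2 fold change of 1, with no test behind it, and counts use the values and not the bounds unless stated.

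Where the probe of a gene was detected on only 1 array of a pair, the fold is given as a bound written "at least N-fold". The bright value was set against the higher of the dim probe's own value and the lowest normalized value of any detected probe on that array. Probes of the same gene differed in log2 fold change with a pooled standard deviation of 0.29 at 10 nM, 0.41 at 20 nM and 0.28 between the doses, over 1467 genes with several detected probes. This spread describes probes and not replicate cultures.

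Before the data were examined, 26 gene lists, the processing alternatives and the rule for named genes were fixed. The rule took the 12 genes farthest from vehicle in each direction at 20 nM that had the same sign at 10 nM, 10 in each direction at 10 nM and 8 in each direction between the doses, all among genes detected on both arrays. It also took 5 genes in each direction per dose detected on 1 array only, up to 4 members of each list with the largest 20 nM values, and a fixed panel. Some genes of that panel are not reported here. The ranking of genes lower at 10 nM passed over 1 gene with a provisional symbol. Genes outside the rule were chosen after their values were seen and appear as examples of lists or families.

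For each list, the median log2 fold change of detected members was placed among the medians of 10000 random lists of named genes of the same size, matched on mean expression in 20 bins. The percentile describes these arrays and is not a test. Because random lists were drawn from the same filtered genes, the percentile is not raised by that filter alone. Both bufalin comparisons share the vehicle array, so their correlation was set beside 100 simulated draws of unchanged arrays that share a vehicle. The simulated noise was taken from the 20 nM against 10 nM differences, which hold dose effects, so it overstates the noise.

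The steps were tested on simulated data made from the vehicle array for the 20 nM against vehicle comparison. This covered 10475 probes, each treated as a gene, so the choice of 1 probe per gene was not tested. A true log2 change of 1.5 came out at a median of 1.46 with 98% called, and one of -1.5 at -1.31 with 78% called. True changes of 3 and -3 came out at 2.86 and -2.57 with 100% called. Of 10275 unchanged probes, 14 passed the threshold, with a noise that was assumed and not measured. The simulation with a shared vehicle gave 329.6 higher and 332.3 lower genes at 10 nM, and 331.3 and 333.3 at 20 nM, with no change. Its noise is overstated for the bufalin arrays and not measured for the vehicle array.

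The alternatives were no background correction, an offset of 50, median scaling or no normalization between arrays, the smaller deposited table, other detection filters, the mean over probes, and thresholds of 1.5-fold and 4-fold. Random lists numbered 2000 in the alternatives. The remaining software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.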

Results

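LNCaP is an established human prostate cancer line, grown from a lymph node metastasis, that responds to androgen. Bufalin is a steroid of toad venom that blocks the sodium pump, Na,K-ATPase. The study asked how transcript levels differ with bufalin concentration after 24 h. Of 47323 probes, 14664 were detected on the vehicle array, 14735 on the 10 nM array and 14612 on the 20 nM array. Without replicates, the number of arrays limits the precision of every value below. Named genes come from a probe set that had been filtered for a difference from vehicle, so genes that differed little are mostly absent from the counts.

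At 10 nM, immediate early genes and p53 targets were among the transcripts farthest above vehicle. CCN1, which encodes a matricellular protein (probe ILMN_2188264), had a log2 fold change of 4.39, with a signal of 188 on the vehicle array and 1993 on the 10 nM array. The stress cytokine gene GDF15, with a signal at 79.1% of the highest on the array, was 9.58-fold higher or more, the MAP kinase phosphatase gene DUSP1 8.94-fold and the growth arrest gene GADD45A 8.86-fold. Far fewer genes were that much lower: MIX23 was 5.38-fold lower and was the only named gene at least 4-fold lower, while 74 were at least 4-fold higher. Part of this contrast may come from the processing. Genes with a detection p-value below 0.05 on the vehicle array alone are not named, while those detected at both doses can be. Decreases also came out smaller than increases in the simulated data.

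Other genes in the leading group at 10 nM were the keratin gene KRT80 (9.77-fold), the epithelial ETS factor gene ELF3 (9.61-fold), the glucocorticoid-induced leucine zipper gene TSC22D3 (9.60-fold) and ENC1 (9.13-fold). PPP1R15A, whose product directs dephosphorylation of the translation factor eIF2-alpha, was 9.01-fold higher, and the growth factor gene HBEGF was 8.18-fold higher. For KRT80 the dimmer probe gave a log2 fold change of 1.14 against 3.29 for the brighter one. Among genes not detected on the vehicle array, GADD45B was at least 21.6-fold higher, TCIM at least 13.9-fold, CREBRF at least 9.83-fold and the endothelin gene EDN1 at least 9.70-fold. The brighter probe of CCN2, the connective tissue growth factor gene, was at least 19.1-fold higher, and its dimmer probe, detected on all 3 arrays, had a log2 fold change of 3.26.

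On the lower side at 10 nM, MSTO1 was 3.31-fold lower, TGDS 3.13-fold, CDCA7 3.06-fold, and EAF2, an androgen-responsive gene, 3.02-fold. GPRIN2 was 3.06-fold lower, TIGD5 2.93-fold, the lysosomal channel gene TPCN2 2.91-fold and TMEM177 2.89-fold. A probe for the ribosomal RNA gene RNA28SN5 was 3.07-fold lower, but it was higher at 20 nM and the other probe of that gene had a log2 fold change of 0.05 at 10 nM. Genes detected on the vehicle array only included THEM4, at least 2.59-fold lower, and POP1, at least 2.55-fold. ARPIN, LRRC45 and EME1 were at least 2.53-fold, 2.47-fold and 2.43-fold lower.

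Of 27 detected p53 targets, 13 were at least 2-fold higher at 10 nM, 0 were lower and 14 were neither. Their median log2 fold change was 0.95, at the 100th percentile of random lists. CDKN1A, the p21 cell cycle inhibitor gene, was higher by a probe at 85.4% of the highest signal, so its fold is not given, and DDB2, a DNA damage recognition gene, was 3.18-fold higher. Of 19 immediate early genes, 15 were at least 2-fold higher, 0 lower and 4 neither, with a median of 1.54. They included the stress transcription factor gene ATF3 (7.69-fold) and IER5 (5.79-fold), while FOS was at least 2.75-fold higher. Secreted factors linked to senescence had 4 of 9 members higher and 0 lower, with a median of 0.99. These were CCL2 (6.69-fold), CXCL8 (5.37-fold), CCL20 (2.30-fold) and MMP10, which was not detected on the vehicle array and is at least 1.84-fold higher at its bound. The list median was 0.55 without background correction.

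Genes of DNA replication and of ribosome biogenesis were lower as lists at 10 nM, mostly by less than 2-fold. Of 31 replication genes, 5 were at least 2-fold lower, 0 higher and 26 neither, with a median of -0.75 at the 0th percentile, or -0.50 in the unnormalized deposited values. The primase gene PRIM1 was 2.79-fold lower and the helicase gene MCM4 2.35-fold lower. Of 26 ribosome biogenesis and MYC target genes, 6 were lower, 0 higher and 20 neither, with a median of -0.62, and MRTO4 was 2.35-fold lower. G2/M genes had a median of -0.36 with 1 of 28 lower, the cyclin gene CCNA2 (2.02-fold). Of 27 genes of the unfolded protein and amino acid stress response, 8 were higher and 0 lower, with a median of 0.28 at the 98.6th percentile, including STC2 (4.54-fold) and DDIT3, the CHOP gene (2.99-fold). Apoptosis regulators had 4 of 20 higher and a median of 0.52, or 0.31 without background correction, led by PMAIP1, the NOXA gene (5.92-fold).

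In all, 528 of 8233 detected genes were at least 2-fold higher at 10 nM and 267 were at least 2-fold lower. The higher share of these calls, 66.4%, was 81.5% without background correction, 77.0% with the larger offset and 86.7% in the unnormalized deposited values. With genes detected on 1 array taken at their bound, the counts were 461 and 241, and without background correction they were 194 and 44. Simulated unchanged arrays gave 329.6 higher and 332.3 lower, so the lower count does not exceed the simulated one. Their noise is overstated for the bufalin arrays and not measured for the vehicle array. Genes with a detection p-value below 0.05 on the vehicle array alone are not named, which can reduce the count of lower genes.

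At 20 nM, the medians of immediate early genes and p53 targets stood farther above vehicle than at 10 nM, and that of replication genes farther below it. CCN1 was 50.1-fold higher, the heme oxygenase gene HMOX1 30.9-fold, PPP1R15A 27.0-fold, ATF3 16.7-fold and GADD45A 16.7-fold. CDCA7 was 10.9-fold lower, the arginine methyltransferase gene PRMT6 9.75-fold, PRIM1 9.54-fold and the splicing factor gene SRSF7 8.57-fold lower. The signal of PRIM1 was 677 on the vehicle array, 312 at 10 nM and 158 at 20 nM.

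The next genes on the higher side at 20 nM were IER5 (15.0-fold), the syndecan gene SDC4 (14.2-fold), TNFRSF12A, the TWEAK receptor gene (13.9-fold), ELF3 (13.2-fold), DUSP1 (12.7-fold), KRT80 (12.2-fold) and the adrenomedullin gene ADM (10.6-fold). Not detected on the vehicle array were GADD45B, at least 42.2-fold higher, CREBRF, at least 27.3-fold, TCIM, at least 26.0-fold, and EDN1, at least 17.4-fold. CCN2 was at least 77.0-fold higher by its brighter probe, and the log2 fold change of its dimmer probe was 5.29.

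On the lower side at 20 nM were MIX23 (9.71-fold), MSTO1 (9.58-fold), TIGD5 (9.29-fold), DBNL (8.55-fold), EAF2 (8.41-fold), the tRNA methyltransferase gene METTL1 (8.37-fold) and ZBTB42 (7.93-fold). The dimmer probe of DBNL gave a log2 fold change of -1.99 against -3.10. TRIM51 had a log2 fold change of -3.39 and TRIM49D1 was at least 5.66-fold lower, but this family holds near-identical copies, so the source of their signal is uncertain. The same holds for FAM86C2P, a pseudogene, at least 5.58-fold lower. EEF2K, a kinase of translation elongation, was at least 7.06-fold lower and the epoxygenase gene CYP2J2 at least 5.93-fold lower. KBTBD11 had a log2 fold change of -2.58 at its bound.

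Of 27 p53 targets, 23 were at least 2-fold higher at 20 nM, 0 lower and 4 neither, with a median log2 fold change of 1.95 at the 100th percentile. They included GADD45A, DDB2 (8.79-fold), GDF15 (7.74-fold or more) and CDKN1A, and MDM2, a ubiquitin ligase gene, was at least 2.97-fold higher. The brighter CDKN1A probe read 20838 at 10 nM and 20842 at 20 nM, near the top of the array's range. Its dimmer probe was not detected on the vehicle array. The 4 below 2-fold were BAX (0.92), CCNG1 (0.89), ZMAT3 (0.67) and RPS27L (0.57). Apoptosis regulators went both ways: of 21, 9 were higher, 4 lower and 8 neither, with a median of 0.87, or 0.39 without background correction. PMAIP1 (log2 fold change of 2.68), BBC3, the PUMA gene (1.99), and BIK (1.82) were higher, as was the survival gene BCL2L1 (1.60), while CASP6 was at -1.62. Of the survival gene MCL1, the brighter probe was 5.04-fold higher and the other had a log2 fold change of 0.36.

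Immediate early genes had 17 of 20 members higher at 20 nM, 1 lower and 2 neither, with a median of 2.32. FOS had a log2 fold change of at least 3.81 and JUNB one of 2.53. The lower member was MYC, a growth transcription factor gene, which was 3.54-fold lower. Senescence-linked secreted factors had 6 of 10 higher and 0 lower, with a median of 1.39, including CXCL8 (8.61-fold), CCL20 (4.56-fold), CCL2 (3.97-fold) and CXCL2, at least 2.02-fold. MMP10 and LIF, not detected on the vehicle array, are at least 1.71-fold and 1.35-fold higher at their bounds. The list median was 1.99 over the 5 members detected on both arrays and 0.45 without background correction. The unfolded protein and amino acid stress list split: 9 of 27 were higher, 1 lower and 17 neither, with a median of 0.29 at the 92.6th percentile, or 0.12 over genes detected on both arrays. PPP1R15A, STC2 (5.26-fold), DDIT3 (4.10-fold) and SESN2, at least 4.75-fold, were higher, whereas the chaperone gene HSPA5 stood at -0.77.

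Of 31 replication genes, 23 were at least 2-fold lower at 20 nM, 0 higher and 8 neither, with a median of -1.42 at the 0th percentile. GINS3 was 7.70-fold lower, CDC45 5.50-fold, MCM4 5.35-fold and MCM2 4.11-fold, all parts of the replicative helicase. The sliding clamp gene PCNA (-0.04) and E2F1 (0.53) were not lower. Of 28 G2/M genes, 11 were lower, 0 higher and 17 neither, with a median of -0.82. The mitotic kinesin gene KIF20A was 4.34-fold lower, CCNA2 3.97-fold, CENPF 3.48-fold and CDC20 2.71-fold, while the cyclin gene CCNB1 was near vehicle at 0.06. Of 26 ribosome biogenesis and MYC target genes, 16 were lower, 0 higher and 10 neither, with a median of -1.09. MRTO4 (5.00-fold), BOP1 (4.78-fold), PPAN (4.50-fold) and NOP16 (3.68-fold) were lower. Cytosolic ribosomal proteins had 1 of 33 lower, RPL13 (2.33-fold), and a median of -0.09, or 0.01 under median scaling. Some of their probes lie at the top of the signal range, where differences can be hidden, such as that of RPS12, with the highest signal on the vehicle array (25603).

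Androgen receptor targets were lower as a list at 20 nM, with large exceptions. Of 23, 9 were at least 2-fold lower, 3 higher and 11 neither, with a median of -0.73 at the 0.25th percentile. EAF2 was 8.41-fold lower, KLK2, a kallikrein gene, at least 4.70-fold, and C1orf116 3.78-fold by its brightest probe, although its probes ranged from -1.92 to -0.62. KLK3, which encodes prostate-specific antigen, was 1.66-fold lower. TSC22D3 was 9.93-fold higher, the protease gene TMPRSS2 3.75-fold higher and the kinase gene SGK1 stood at 1.90. Luminal prostate markers had 2 of 14 higher and 3 lower, with a median of -0.10, or 0.06 under median scaling. The ETS factor gene SPDEF was 4.57-fold lower and STEAP2 3.21-fold lower. STEAP1 was 2.26-fold lower by its brightest probe, but another of its probes gave -0.12. Over androgen receptor targets detected on both arrays, the median was -0.52, at the 3.13th percentile, and over all of them it was -0.40 without background correction.

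Genes of the sodium pump and cation transport had 2 of 7 detected members higher at 20 nM and 1 lower, with a median of 0.60, or 0.34 without background correction. The pump's beta subunit gene ATP1B1 was 2.84-fold higher at 10 nM and 2.86-fold higher at 20 nM by its brighter probe, and its other probe gave log2 fold changes of 0.56 and 0.88. NFAT5, an osmotic stress transcription factor gene, was 6.12-fold higher at 20 nM. ATP2B4, a calcium pump gene, was at least 1.85-fold lower by its brighter probe, and its other probe gave a log2 fold change of -0.22.

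Other stress and metabolic lists had members on both sides or few past 2-fold at 20 nM, and their medians lay within the central 95% of random lists, except for heat shock genes in 3 of 11 settings. Of 17 heat shock genes, 4 were lower and 3 higher, with a median of -0.42, or -0.16 under median scaling: the chaperone genes HSPA8 and HSPH1 were 3.31-fold and 3.29-fold lower, and DNAJB4 was 4.64-fold higher. Cholesterol synthesis had 4 of 17 lower and 3 higher, with a median of -0.24, and ranged from SQLE, 4.39-fold lower, to INSIG1, 4.43-fold higher. HMGCS1 stood at -0.33. Oxidative stress (NRF2) genes had 3 of 19 higher and a median of 0.07: AKR1C3 was 4.54-fold higher, while NQO1 stood at -0.22. Hypoxia and glycolysis genes had 3 of 26 higher and 2 lower, with a median of -0.06, or 0.09 under median scaling. Interferon-stimulated genes had 1 of 13 higher, IRF1 (5.05-fold), and a median of 0.32.

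No detected gene of oxidative phosphorylation (21, median 0.23, or 0.45 under median scaling) or of the metallothionein and zinc list (7, median 0.67) passed the threshold at 20 nM. Histone genes had 2 of 14 higher, H2BC5 (6.38-fold) and H2BC21 (3.63-fold), and a median of 0.48. Steroid hormone enzymes had 3 of 11 higher and 1 lower, with a median of -0.29. Of 12 housekeeping genes, 2 were lower, TUBB (2.89-fold) and HPRT1 (2.20-fold), and POLR2A was 2.93-fold higher, with a median of -0.18. Markers of other cell types were mostly unnamed or undetected. Basal epithelial markers had 0 detected members. Neuroendocrine markers had 3, none past 2-fold and with a median of 0.54, and stromal markers had 4, with a median of 0.52 and TAGLN 2.42-fold higher. Leukocyte markers had 3, with a median of 1.71, or 0.92 without background correction. They were CD14, at least 2.91-fold higher, HLA-DRA, 3.26-fold higher with its other probe at 0.64, and CD68, at 0.49 with its other probe at 1.43.

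In all, 1224 of 8346 detected genes were at least 2-fold higher at 20 nM and 1386 were at least 2-fold lower, or 1105 and 1241 with bounds and 552 and 544 without background correction. The simulated unchanged arrays gave 331.3 and 333.3. Of the 22 lists with at least 5 detected members, 4 lay above the central 95% of random lists and 4 below it. If lists were random draws of genes, 1.1 would lie outside. The lists share members and arrays, and their members may vary together, so that number can be too low and is not a test.

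**Figure D1:**
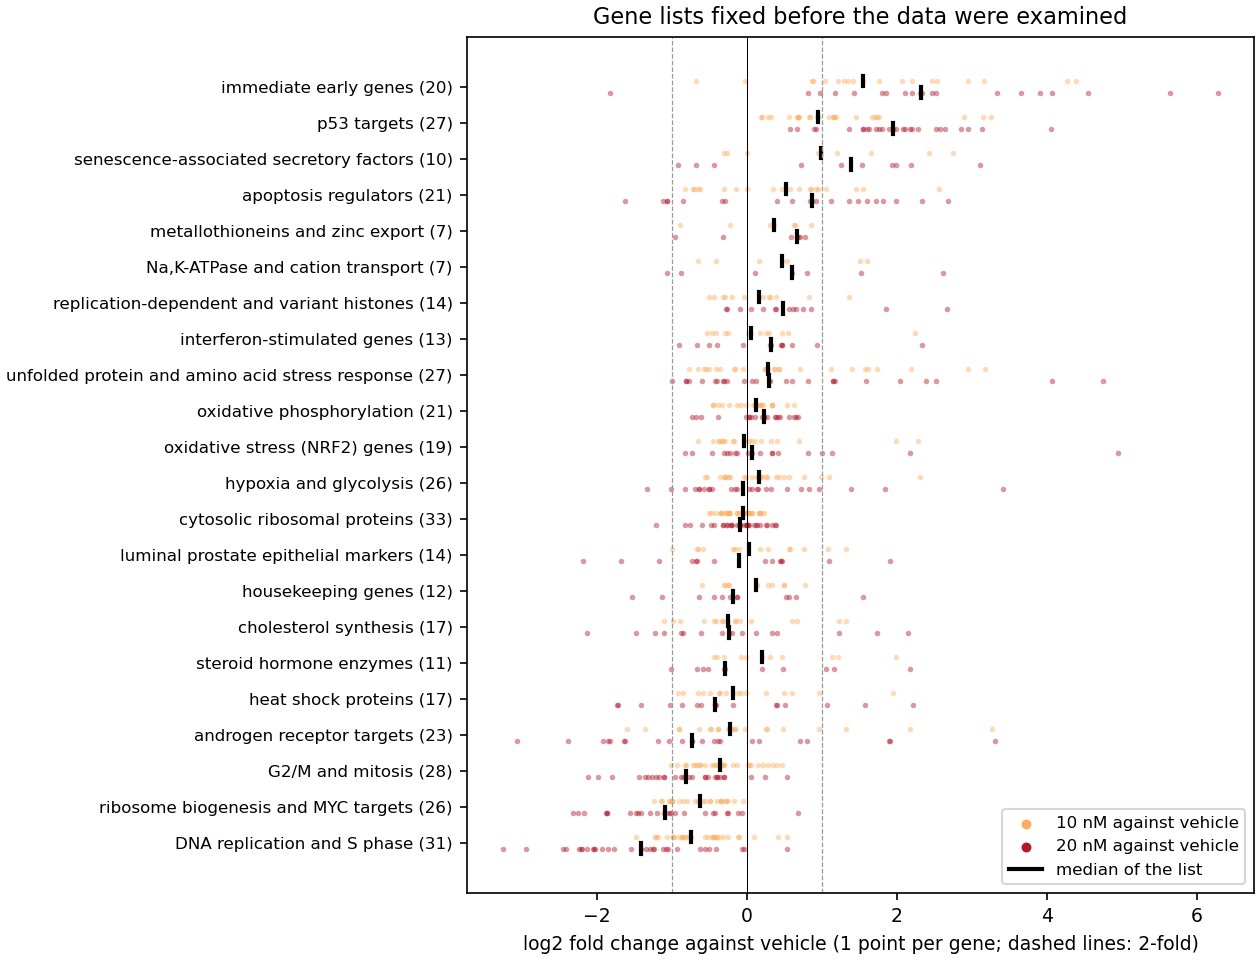
Log2 fold change against vehicle (x axis) of each detected member of the 22 fixed gene lists with at least 5 detected genes at 20 nM (y axis, number of genes in brackets). Points are genes at 10 nM (orange) and 20 nM (red), black bars are list medians, and dashed lines mark 2-fold: the p53 median lies at 0.95 and 1.95, that of DNA replication at -0.75 and -1.42.

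Between the doses, the medians of replication genes and androgen receptor targets were lower at 20 nM than at 10 nM, and those of p53 targets and immediate early genes were higher, although many members were within 2-fold. HMOX1 was 6.36-fold higher at 20 nM than at 10 nM, the LIM domain gene FHL2 5.28-fold, CEP85L 5.10-fold, FOS 5.09-fold and CCN2 4.03-fold. TRIM51 was 6.31-fold lower, the glucose-6-phosphate transporter gene SLC37A4 4.10-fold, SRSF7 3.98-fold and CPOX, a heme synthesis gene, 3.97-fold lower.

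HIC2 (3.53-fold) and ZNF750, an epidermal transcription factor gene (3.52-fold), were also higher at 20 nM than at 10 nM. The RNA28SN5 probe was 28.6-fold higher, while the other probe of that gene gave a log2 difference of 0.73. Some lower genes had stood above vehicle at 10 nM: the phospholipase gene PLA2G2A was at least 6.31-fold above vehicle at 10 nM and 6.09-fold lower at 20 nM than at 10 nM. RTKN, which encodes rhotekin, was 4.53-fold lower between the doses, EPM2AIP1 4.09-fold and the kinase gene TAOK3 4.06-fold lower. TAOK3 had log2 fold changes against vehicle of 1.39 at 10 nM and -0.63 at 20 nM.

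Of 31 replication genes, 12 were at least 2-fold lower at 20 nM than at 10 nM and 0 higher, with a median log2 difference of -0.87, or -0.55 without background correction. Of 23 androgen receptor targets, 6 were lower and 0 higher, with a median of -0.50 at the 0.02nd percentile, or -0.31 without background correction and -0.34 over genes detected on both arrays. For this list the 10 nM median against vehicle was -0.23, at the 11.5th percentile. Of 27 p53 targets, 9 were higher and 0 lower, with a median of 0.87, or 0.53 without background correction. The dimmer CDKN1A probe was 1.07 log2 units higher, and the brighter one lies near the top of the signal range. GDF15 stood at -0.31, with signals at 79.1% of the highest at 10 nM and 65.1% at 20 nM. Immediate early genes had 9 of 20 higher and 1 lower, with a median of 0.92. The histone list had a median of 0.43, at the 99.9th percentile, with 2 of 14 higher. The oxidative stress (NRF2) list had a median of 0.21, at the 98.4th percentile, with HMOX1 alone past 2-fold among 19, and lay above the central 95% of random lists in 8 of 11 settings. Ribosome biogenesis and MYC targets had a median of -0.47 with 4 of 26 lower, and G2/M genes one of -0.42 with 2 of 28 lower. Senescence-linked secreted factors went both ways, with 0 of 9 past 2-fold and a median of -0.11: CXCL2 and CCL20 stood at 0.99 and CXCL8 at 0.68, while CCL2 stood at -0.75.

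In all, 223 of 8195 detected genes were at least 2-fold higher at 20 nM than at 10 nM and 395 were at least 2-fold lower. The higher share of these calls, 36.1%, was 26.3% without normalization between arrays, 29.7% in the unnormalized deposited values and 41.0% under median scaling. Without background correction, 39 were higher and 76 lower.

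Most genes past 2-fold at 10 nM were past it in the same direction at 20 nM: 463 of the 528 higher and 238 of the 267 lower genes. Of the 528 higher genes, 409 stood farther from vehicle at 20 nM, and their median log2 fold change was 1.29 at 10 nM and 1.83 at 20 nM. Of the 267 lower genes, 228 stood farther, with medians of -1.14 and -1.85. Only 1 gene passed 2-fold in opposite directions, RNA28SN5. Prostate genes followed different courses: TMPRSS2 read 1492, 3668 and 5800 on the vehicle, 10 nM and 20 nM arrays, and EAF2 read 484, 226 and 144.

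**Figure D2:**
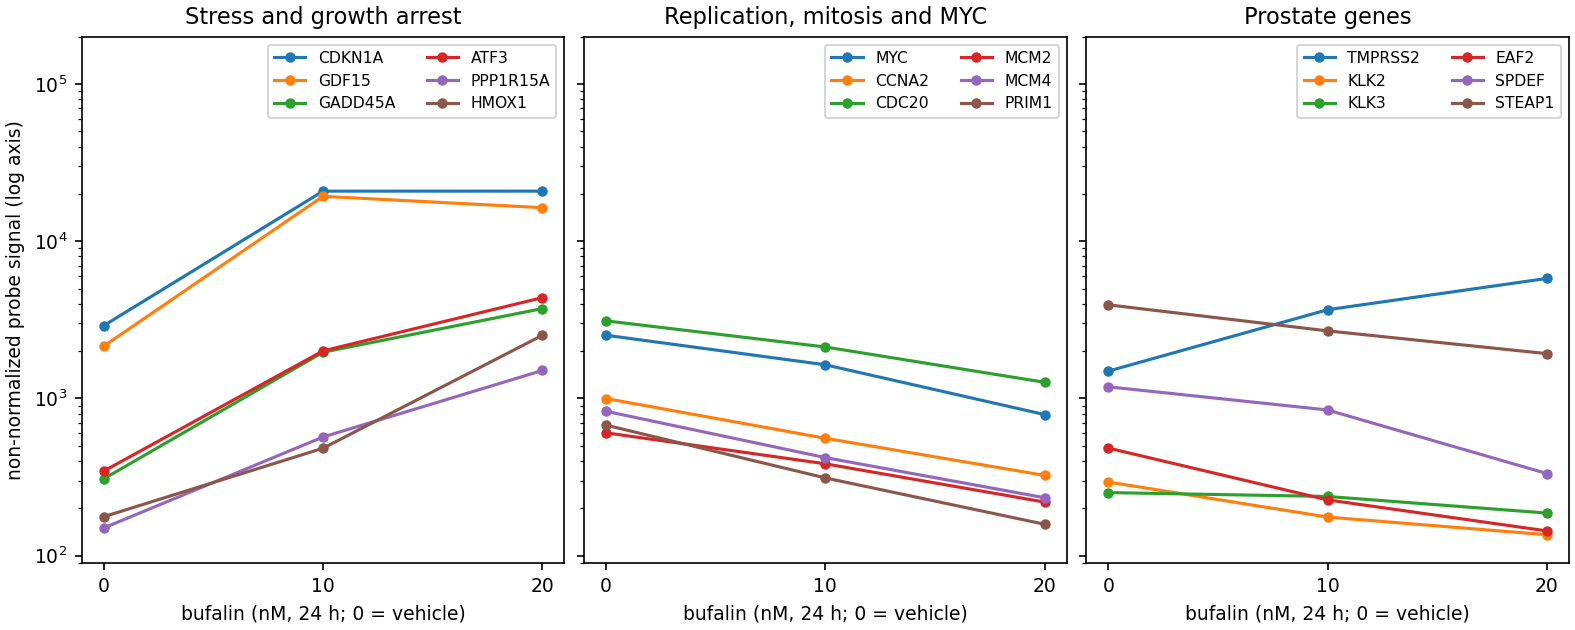
Non-normalized probe signal (y axis, log scale) against bufalin concentration in nM (x axis, 0 is vehicle) for selected genes, 1 array per point and 1 line per gene. CDKN1A reads 2905, 20838 and 20842, MYC reads 2524, 1638 and 790, and the fitted background of the vehicle array is 112.9.

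Across 8431 genes detected in either comparison, the log2 fold changes at 10 and 20 nM had a Pearson r of 0.869 and a Spearman rho of 0.861, and 88.1% had the same sign. Genes are not independent replicates, and both sets of fold changes use the same vehicle array. Over all 16508 detected probes, named or not, 82.2% had the same sign. Unchanged arrays simulated with a shared vehicle gave an r of 0.498 and the same sign for 66.6% of genes. Those simulated values follow from the shared vehicle and the equal noise. The simulated genes did not pass through the filter for a difference from vehicle that the named genes had passed. Of the genes past 2-fold at 10 nM, 87.7% of the higher and 89.1% of the lower ones were past it at 20 nM, against 23.6% and 23.7% in the simulation. Independent lists of the observed sizes would share 76.7 higher and 43.9 lower genes. The covariance was 0.571 against 0.159 in the simulation, a difference of 0.412. With 1 vehicle array the controls could not be split, so part of the overlap may come from the shared array. The simulation gave all arrays equal noise and held no deviant vehicle array. It therefore cannot separate dose effects from the noise of that array.

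**Figure D3:**
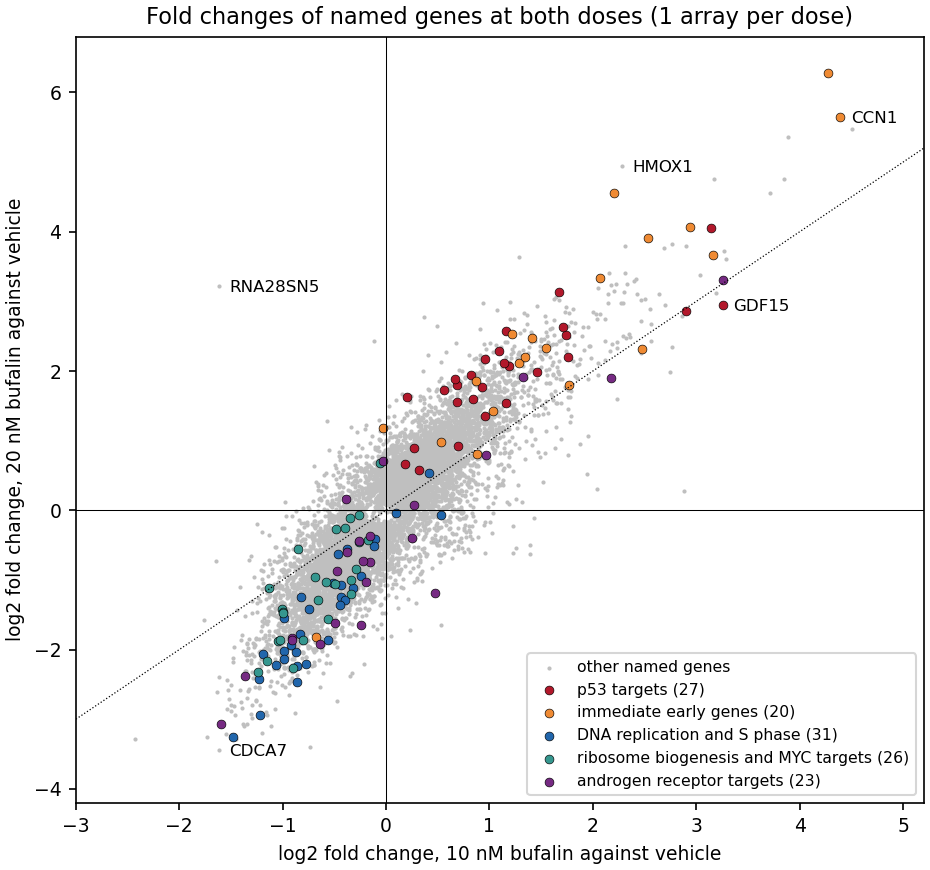
Log2 fold change at 20 nM (y axis) against that at 10 nM (x axis) for named genes detected in either comparison, with 5 fixed gene lists in colour and equal values on the dotted line. Red p53 targets and orange immediate early genes lie mostly in the upper right, blue replication genes in the lower left, and RNA28SN5 alone lies far in the upper left, at -1.62 and 3.22.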

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

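Of the tests in this part, both for RNA28SN5, that for GDF15 and that of the submitters' filter were chosen only after the result was seen. RNA28SN5, a gene of 28S ribosomal RNA, was the only gene past 2-fold in opposite directions at the 2 doses: its probe had a log2 fold change of -1.62 at 10 nM and 3.22 at 20 nM. The difference between the doses was not tested. Its other probe gave 0.05 and 0.79, so most of the difference may be a reading of the 1 probe. If carry-over of RNA without poly(A) tails differed between arrays, other such RNAs would follow. At 20 nM, 69 detected RNAs of this kind had a median of -0.19, and at 10 nM, 67 had one of -0.34. Between the doses, however, 63 had a median of 0.26, at the 99.5th percentile, with 11 at least 2-fold higher and 0 lower. Carry-over therefore stays open. Single members were mixed: RN7SK stood at 2.13 and RNU6ATAC at 2.11 at 20 nM, whereas RNA18SN5 stood at -0.85.

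CDKN1A and GDF15 were no higher at 20 nM than at 10 nM, unlike most p53 targets. The brighter CDKN1A probe reached 85.4% of the highest signal on the 10 nM array, so saturation may hide a further step. Its dimmer probe, far from that limit and detected at both doses, was 1.07 log2 units higher at 20 nM than at 10 nM. GDF15 reached 79.1% of the highest signal, but it was 0.31 log2 units lower at 20 nM, slightly more than the spread of 0.28 between probes, so saturation alone leaves this open.

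Named genes come from probes filtered for a difference of at least 10%, a rule found from the values. The p53 targets lay at the 100th percentile of random lists drawn from the same filtered genes, so the filter alone did not give random lists such a median. This percentile was already known and is not a separate check. The filter can still enlarge the median, since members that differ little are not named: 27 of 32 listed p53 targets were named.

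Probes with no gene name here, which no comparison above uses, were also counted. At 10 nM, 110 of 5407 detected ones were at least 2-fold higher and 115 lower, and at 20 nM, 369 of 5577 were higher and 357 lower. Simulated unchanged arrays, over all 16508 detected probes, gave 479.8 higher and 479.4 lower at 10 nM. That is a larger share than observed. It cannot decide whether unnamed probes differed at 10 nM, because the 10% filter left probes close to vehicle unnamed. The simulated noise is also overstated. At 20 nM the simulation gave 477.6 and 475.4, a smaller share than observed. The probe ILMN_3243644 had log2 fold changes of 1.86 at 10 nM and 3.79 at 20 nM, and ILMN_1786024 had -1.10 and -2.62.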

How the results depend on the processing

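No result changed sign as a called value. With 1 array per group, no array could be left out. No paired analysis was possible because each treatment had 1 array and the labels carry no pairing. Dropping the detection filter or easing it to 0.05 added no called gene, so neither bears on stability. The p53, immediate early, replication, ribosome biogenesis and G2/M medians stayed outside the central 95% of random lists in all 11 settings for both doses, while androgen receptor targets at 20 nM did so in 9. These 11 settings include the main one and the dropped and eased detection filters, so fewer of them bear on stability. Dim genes are limited by background, since a median signal of 119.5 on the vehicle array stands beside a fitted background of 112.9. Of the comparisons of named genes with their alternatives, 598 moved by more than the spread between probes and 3265 did not, mostly where background was left in or the offset was larger. Those settings shrink fold changes by construction.

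Counts of genes at least 2-fold higher or lower are given in the order 10 nM higher, 10 nM lower, 20 nM higher, 20 nM lower, 20 nM against 10 nM higher and lower. They were 528, 267, 1224, 1386, 223 and 395. At 1.5-fold they were 1410, 1337, 2296, 2617, 1037 and 1353, and at 4-fold 74, 1, 236, 163, 9 and 8. Without background correction they were 194, 44, 552, 544, 39 and 76, and with the smaller deposited table they were 208, 32, 558, 539, 35 and 83. With an offset of 50 those that moved were 318, 95, 893 (20 nM lower), 90 and 168. Over all detected probes, 436 were lower at 10 nM, 1979 higher at 20 nM and 414 higher at 20 nM than at 10 nM, because more probes were counted. Requiring detection on all 3 arrays left 146 higher at 20 nM than at 10 nM, because fewer genes were counted. The correlation of the 10 nM and 20 nM fold changes across genes, 0.869, was 0.845 over all probes, 0.885 without background correction, 0.879 with an offset of 50 and 0.884 in the smaller deposited table.

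Without background correction, list medians at 10 nM were 0.68 for p53 targets, 0.55 for senescence-associated secretory factors, -0.53 for DNA replication and S phase, 1.103 for immediate early genes and 0.31 for apoptosis regulators. At 20 nM they were 1.41 for p53 targets, 0.45 for senescence-associated secretory factors, -0.40 for androgen receptor targets, -1.04 for DNA replication and S phase, 1.87 for immediate early genes, 0.39 for apoptosis regulators and 0.92 for leukocyte markers. For 20 nM against 10 nM they were 0.53 for p53 targets, -0.31 for androgen receptor targets, -0.55 for DNA replication and S phase, 0.74 for immediate early genes and -0.32 for ribosome biogenesis and MYC targets.

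In the smaller deposited table, list medians at 10 nM were 0.70 for p53 targets, 0.56 for senescence-associated secretory factors, -0.50 for DNA replication and S phase, 1.102 for immediate early genes, -0.46 for ribosome biogenesis and MYC targets and 0.33 for apoptosis regulators. At 20 nM they were 1.45 for p53 targets, 0.45 for senescence-associated secretory factors, -0.43 for androgen receptor targets, -1.03 for DNA replication and S phase, 1.88 for immediate early genes, 0.37 for apoptosis regulators and 0.92 for leukocyte markers. For 20 nM against 10 nM they were 0.54 for p53 targets, -0.34 for androgen receptor targets, -0.57 for DNA replication and S phase, 0.77 for immediate early genes and 0.11 for apoptosis regulators.

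With an offset of 50, immediate early genes had a list median of 1.33 at 10 nM, and p53 targets had 1.53 and senescence-associated secretory factors 0.74 at 20 nM. For 20 nM against 10 nM, p53 targets had 0.75 and DNA replication and S phase -0.71. Under median scaling, cytosolic ribosomal proteins had -0.13 at 10 nM, heat shock proteins -0.16 and oxidative phosphorylation 0.45 at 20 nM. For 20 nM against 10 nM, cytosolic ribosomal proteins had 0.18, oxidative phosphorylation 0.22 and housekeeping genes a list median of -0.026, and the cause was not tested. Over genes detected on all 3 arrays, and likewise on both arrays compared, the medians were 1.99 for senescence-associated secretory factors at 20 nM, and -0.34 for androgen receptor targets and -0.20 for fibroblast and stromal markers for 20 nM against 10 nM, because fewer genes were counted.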

Other observations

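Of the tests in this part, that of the zinc finger genes was chosen only after the result was seen, and 17 further gene lists were made after part of the values had been seen, some around genes already ranked, so they are not independent of those genes. Of 10 circadian clock genes, 9 were at least 2-fold higher at 20 nM, with a median log2 fold change of 1.90 (1.23 at 10 nM): TEF stood at 3.06, BHLHE40 at 2.73 and CRY1 at 2.49, while DBP stood at 0.37. Autophagy and lysosome genes had 7 of 18 higher and 1 lower, with a median of 0.87, including GABARAPL1 (2.74), NEU1 (2.49) and MAP1LC3B (2.24), with CTSL at -1.51. NF-kappa-B targets had 4 of 10 higher and a median of 0.97, including REL (2.02) and TNFAIP3 (1.63). Of 5 YAP and TAZ targets, 3 were higher and 1 lower, with a median of 1.82: ANKRD1 stood at 3.25, LATS2 at 2.59 and WWC1 at -1.19. Dual-specificity phosphatases had 6 of 13 higher and 3 lower, with a median of 0.88, including DUSP5 (3.32) and DUSP8 (3.19).

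Mitochondrial ribosomal proteins had 13 of 68 lower at 20 nM and 0 higher, with a median of -0.64, including MRPS26 (-2.35) and MRPL17 (-2.27). RNA exosome subunits had 5 of 10 lower and a median of -0.96, with EXOSC2 at -2.76. Chaperonin subunits had 4 of 8 lower and a median at the 0.24th percentile of random lists, with CCT5 at -1.75. SR splicing factors had 5 of 11 lower and 1 higher, with a median of -0.49 and SRSF3 at -2.16. Cytosolic aminoacyl-tRNA synthetases had 4 of 14 lower and a median of -0.38, and proteasome subunits 2 of 28 lower and a median of -0.42. Kelch-like genes had 4 higher and 4 lower of 19, with a median of -0.48, although KLHL24 stood at 3.15 and KLHL28 at 3.10. RNAs without poly(A) tails had 14 higher and 6 lower of 69. The medians of SR splicing factors, aminoacyl-tRNA synthetases, kelch-like genes and RNAs without poly(A) tails, at the 6.52nd, 9.69th, 10.6th and 48.3rd percentiles, lay within the central 95% of random lists.

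Because TSC22D3, SGK1 and DUSP1 respond to glucocorticoids and bufalin is a steroid, a hypothesis of induction of the glucocorticoid receptor type was tested with targets not seen before. Their median at 20 nM was 1.35, which meets the prediction. Of the 6, 5 were at least 2-fold higher, including ERRFI1 (2.98) and CEBPD (1.71), and 1 was at least 2-fold lower. FKBP5, a strong target of that receptor, stood at -1.83, so general stress could give the same pattern. Over all 10 targets of the glucocorticoid receptor list, the median was 1.56. TSC22D3, SGK1 and FKBP5 are also in the fixed androgen receptor list, and DUSP1 is in the immediate early list. Meeting the prediction therefore does not single out the glucocorticoid receptor, whose own level is not given here.

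Of genes with ZNF symbols, ZNF750 was the only one ranked among those higher at 20 nM than at 10 nM. The hypothesis of a family-wide difference was tested on the other ZNF genes. Their 20 nM against 10 nM median lay at the 99.9th percentile of random lists, but it was only 0.15 over 200 genes, with 15 higher and 7 lower. Against vehicle at 20 nM, all 215 detected ZNF genes had a median of -0.01, and the 214 outside the ranking -0.06. At 10 nM, 206 detected ZNF genes had a median of -0.17, so the list median was not above vehicle at either dose.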
